A study of Mus musculus with 18 samples.

How the data were processed

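CUT&RUN, in which an antibody directs a nuclease to cut and release the DNA around a chromatin mark, was performed on single-cell suspensions of mouse epidermis with a Cell Signaling kit, and libraries were made with NEBNext Ultra reagents and sequenced as 37 bp paired-end reads, per the labels' protocols. The 18 libraries form 6 groups of 3: IgG, H3K36me2 and H3K27me3, each from Krt14-Cre-negative and Krt14-Cre-positive mice that carry the LSL-H3K36M construct, per the labels. Animal numbers in the labels give 6 animals, 3 per genotype, each with 1 library per antibody. No animal belongs to both genotypes. The Cre-positive mice are called mutant below and the Cre-negative mice WT, as the column names of the tables have it.

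Reads were aligned with Bowtie2 to GRCm38 (mm10) and compared with DiffBind, DESeq2 and SICER, per the submitters' processing notes, which give no versions. Duplicate handling, spike-in, blacklist and peak caller are not given in the sources used here. The values used were 3 tables of comparisons, and none of them holds a column per library. The depth of single libraries is therefore unknown, the IgG libraries were not analysed here, and no new test across animals was made.

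For H3K36me2 and for H3K27me3, the authors deposited DiffBind results for windows of 401 bp, with log2 mean normalised reads over all libraries and per genotype, per the file headers. The fold in these tables is a log2 fold of mutant over WT, deposited in a shrunken form. Each window also has a p-value and an FDR, per the file headers. The ratio of FDR to p in the first row gave 18072 windows tested for each mark, of which 730 are listed for H3K36me2 and 4285 for H3K27me3. The overall mean equalled the mean of both genotype means within 1e-06 in 716 of the 730 H3K36me2 windows and in 4178 of the 4285 H3K27me3 windows. The remaining windows have a genotype mean at the floor of 1 read, so their differences depend on that floor. Means per window are given below as normalised reads, converted from log2.

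For H3K36me2 the authors also deposited a SICER2 table of 13409 islands in steps of 200 bp, with read counts in 1 column per genotype, per the file headers. The normalised columns were checked to be RPM (reads scaled to depth), and each deposited count divided by its RPM gave 59539924 mutant reads and 47361190 WT reads. The deposited fold is the ratio of depth-scaled counts with 1 read added to each. Each island has a p-value and an FDR in each direction, per the file headers. How the 3 libraries of a genotype were merged is not given in the sources used here. The SICER2 test compares the reads of the pools, not the animals of each genotype, and islands are called higher or lower below in that sense. At FDR 0.05 no island was called in both directions.

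A region was called changed at the authors' FDR under 0.05. This rule, the gene lists, the rule for named genes and the planned comparisons were fixed before the data were examined. No H3K36me2 DiffBind window passed it, so windows with a nominal p under 0.05 were described as well, a choice made after the data were seen. Genes came from the RefSeq table of GRCm38.p6, with 21896 protein-coding genes. No gene assignment is among the columns used, so a region was assigned to each gene whose body it overlapped or lay within 5 kb of, chosen after the data were seen. The RefSeq table used gives no strand, so distances were taken to either end of a gene, not to a transcription start site. "In gene bodies" means an overlap of at least 1 bp with a protein-coding gene.

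Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Read ratios of islands carry exact binomial 95% intervals without the added read. PCR copies are not independent molecules, and the intervals leave out differences between animals. Direction and location were compared with 2-sided Fisher's exact tests over regions, and gene lists with 2-sided Fisher's exact tests over the protein-coding genes. Benjamini-Hochberg adjustment covered the 14 lists, both directions and both tables together. Regions and genes are not independent replicates. Overlaps between marks were compared with 1000 random placements of the H3K36me2 regions, with their widths kept. Each region was placed on its own chromosome between the outermost listed regions, and tests were 1-sided, for which the smallest p is 0.000999. The H3K27me3 windows stayed in place. The H3K36me2 table of DiffBind served shared windows, and SICER2 served islands.

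Named genes were, per table, the 10 with the largest rise and the 10 with the largest fall past the FDR and the 5 with most regions changed one way. Up to 4 members of each list by FDR and up to 10 genes lower in H3K36me2 and higher in H3K27me3 were added. The 14 lists were basal and follicle stem cell genes, epidermal differentiation genes, gland and sebaceous genes, Hedgehog genes, WNT genes, BMP and TGF-beta genes, FGF, EGF and Notch signalling genes, Polycomb-bound developmental regulators, H3K36 and Polycomb enzymes, squamous carcinoma genes, and markers of melanocytes, immune cells, fibroblasts and endothelium, and Merkel cells. Islands near list genes were also adjusted over the list alone, from the deposited p-value of each direction. For windows this was not done, since those not called are not among the rows used.

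Alternatives were a stricter FDR of 0.01, an absolute log2 fold of at least 1, autosomes only, counts of genes and base pairs, gene bodies without flanks, genes with any island as background, and other overlap rules. For islands, the fold was also divided by the median fold of all islands, followed by a 2-sided exact binomial test of the 2 pooled counts with Benjamini-Hochberg adjustment. On counts simulated for the 13409 islands, this test recovered 116 of 200 islands changed 1.5-fold (58%, with 4 false calls) and 196 of 200 changed 2-fold (98%, with 3 false calls). The simulated counts had Poisson counting error and a common offset only, without a spread between animals or PCR copies. The false calls are therefore not an error rate for the real pools. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.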

Results

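H3K36me2 and H3K27me3 were profiled by CUT&RUN in the epidermis of mice in which Krt14-Cre switches on H3K36M, a histone H3 with lysine 36 replaced by methionine that blocks H3K36 methylation. Each mark was measured in 3 Cre-positive (mutant) and 3 Cre-negative (WT) animals, and 3 IgG libraries per genotype were not analysed here. The island table rests on 59539924 mutant and 47361190 WT reads, of which 5.71% and 6.58% lie in islands. A median island held 170 mutant and 165 WT reads over 5000 bp. Windows of 401 bp in the DiffBind tables are known only as genotype means, so the spread between animals is not given beside them. All positions are on GRCm38.

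The first comparison asked where H3K36me2, the mark that H3K36M acts on, differed between mutant and WT epidermis. Most called islands were lower in the mutant: 7791 of 13409 islands (58.1%, 95% interval 57.3 to 58.9) covering 49.6 Mb were lower, and 2322 (17.3%, 16.7 to 18.0) covering 11.1 Mb were higher. This balance depends on the scaling: the median log2 fold of all islands was -0.30, and relative to that median it reversed, with 1793 islands lower and 3675 higher. Division by the median removes a general loss of H3K36me2 along with any scaling difference, so it cannot tell them apart. Calls lost relative to the median below have the same limit. The median lower island had 0.709 times the WT level and the median higher island 1.36 times. Islands outside gene bodies carried most of the decrease, and higher islands lay mainly inside genes. The remaining 3296 islands passed the FDR in neither direction. An exact binomial test at the deposited scaling, which allows for counting error in both pools, kept fewer of these calls. It kept 6305 of the 7791 lower and 1367 of the 2322 higher islands. The deposited island FDRs, which are those given below, are thus less strict than that test, and neither covers the spread between animals.

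Among the lower islands, the lowest fold was at Wnt2, which encodes a secreted WNT ligand, on chromosome 6 from 17999801 to 18000200. In the authors' deposited table it had 11 mutant and 48 WT reads, a fold of 0.195 and an FDR of 2.97e-19. Next came Samd12 (fold 0.384), Immp2l, a mitochondrial inner membrane peptidase gene (0.415), Ptprn2, a secretory granule protein gene (0.417), and Cstdc6 (0.429) in the authors' deposited table. Fam169a (0.437), Arhgef28 (0.438), Fhit, a diadenosine triphosphate hydrolase gene (0.442), Klk5, a protease gene of the outer epidermis (0.447), and Cd96, a lymphocyte receptor gene (0.455), completed the 10 lowest among islands within 5 kb of a protein-coding gene, while 19 islands farther from genes had folds below that of Cd96. Very long genes held the most lower islands: 24 at Adgrv1, a giant adhesion receptor gene, 21 at Macrod2, an ADP-ribosylhydrolase gene, 15 at Maml2, a Notch coactivator gene, 13 at Rora, a nuclear receptor gene, and 12 at Cmss1.

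Among higher islands within 5 kb of a gene, Arhgap10 came first, with 100 mutant and 28 WT reads and a fold of 2.77 in the authors' deposited table (FDR 4.33e-17). Away from genes, 1 island on chromosome 6 from 114553201 to 114553400 had a larger fold, 4.09 in the authors' deposited table. Krt14, the basal keratin gene whose promoter drives the Cre, had 1 island, on chromosome 11 from 100207401 to 100208000. It had 57 mutant and 16 WT reads, a fold of 2.71 and an FDR of 5.30e-10 in the authors' deposited table. The exact binomial interval of that read ratio ran from 1.60 to 5.29. An island in the type I interferon cluster on chromosome 4, at Ifnz, had 36 against 10 reads (fold 2.68 in the authors' deposited table). Further large folds in the authors' deposited table were 2.30 at Ngly1, which removes N-glycans, 2.29 at Rev3l, a translesion polymerase gene, 2.21 at Ago3, an Argonaute gene, and 2.21 at Osbpl3. Aopep, an aminopeptidase gene, Tenm2, a teneurin gene, Clec16a, an autophagy gene, and Dennd1a, an endocytosis gene, each held 7 higher islands.

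Epidermal genes were found on both sides. Of 38 epidermal differentiation genes, 15 had a lower island and 4 a higher one, with 3 genes counted in both. The excess of lower genes had an adjusted p of 2.40e-04 by Fisher's exact test (odds ratio 4.72). Of the 38, 19 had any island, against 20.6% of all genes, and among genes with an island the lower ones were not called (adjusted p = 0.709). After division by the median fold of all islands, 3 of the 38 had a lower island (adjusted p = 0.172). Sprr1a, a cornified envelope precursor gene, had a fold of 0.488 (FDR 1.83e-30) in the authors' deposited table, Dsg1c, a desmosomal cadherin gene, 0.529, Casp14, the caspase of cornification, 0.615, and Ivl, the involucrin gene, 0.696. Sprr1a and Ivl lie in the epidermal differentiation complex on chromosome 3, where 35 of 38 islands were lower. Neighbouring genes of the list are thus not independent in the Fisher's exact test. Of 23 basal and follicle stem cell genes, 10 had a higher island (odds ratio 9.98, adjusted p = 4.84e-05) and 8 a lower one (odds ratio 3.85, adjusted p = 0.0244), with 5 genes counted in both. The lower islands were not called with gene bodies only (6 of 23, adjusted p = 0.0700), and relative to the median fold 0 of the 23 had one. Among genes with an island, which 13 of the 23 were, the lower islands were not called either (adjusted p = 1.0) and the higher ones were (odds ratio 6.25, adjusted p = 0.0488). Besides Krt14, the deposited folds in the authors' deposited table were 1.47 at Trp63, the gene of the epidermal regulator p63, 1.83 at Tcf7l2, a WNT effector gene, and 1.70 at Lgr6, a stem cell receptor gene. The direction of neither list differed from that of all genes (adjusted p = 0.651 and 0.706).

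Signalling genes were mixed. Islands in both directions were found at 3 Hedgehog, 1 WNT, and 2 BMP and TGF-beta genes. They were also found at 2 FGF, EGF and Notch genes and at all 3 gland genes with a higher island. Each fold below is that of 1 island, not of the whole gene. Of 16 Hedgehog genes, 7 had a higher island (odds ratio 10.1, adjusted p = 5.04e-04) and 4 a lower one (adjusted p = 0.255). With gene bodies only, 4 had a higher and 4 a lower island, and the higher ones were not called (adjusted p = 0.0852). Any island was found at 8 of the 16, and among genes with an island 7 of these 8 had a higher one (Fisher's exact test, adjusted p = 0.0488). Kif7, a ciliary regulator of GLI proteins, had a fold of 1.62 in the authors' deposited table, while Cdon, a Hedgehog co-receptor gene, had 0.541, Disp1, which releases Hedgehog ligands, 0.672 and Gli3, a Hedgehog transcription factor gene, 0.698. WNT genes had 10 of 49 lower and 5 higher (adjusted p = 0.191 and 0.638), with Wnt16 at 0.611, the antagonist gene Sfrp1 at 0.604 and the receptor gene Fzd6 at 0.615 in the authors' deposited table. BMP and TGF-beta genes had 10 of 40 lower and 6 higher (adjusted p = 0.0991 and 0.163), with the ligand gene Tgfb2 at 0.666, the receptor genes Bmpr1b at 0.602 and Tgfbr2 at 0.701, and the protease gene Bmp1 at 1.72 in the authors' deposited table. FGF, EGF and Notch signalling genes had 6 of 41 lower and 3 higher (adjusted p = 0.882 and 1.0), among them the EGFR ligand gene Ereg at 0.461, Hes1 at 0.775, Jag1 at 0.689 and Egfr at 1.30 in the authors' deposited table. Gland and sebaceous genes had 4 of 40 lower and 3 higher (both adjusted p = 1.0), including the prolactin receptor gene Prlr at 0.642, Edaradd at 0.740, Fgfr2 at 1.65 and the lipid droplet gene Plin2 at 1.24 in the authors' deposited table.

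Polycomb-bound developmental regulators were short of islands: 10 of 154 had any (6.49%, against 20.6% of all genes), with 4 lower (odds ratio 0.191, adjusted p = 3.16e-04) and 3 higher (odds ratio 0.255, adjusted p = 0.0359). Among the 58 of at least 10 kb neither was called (adjusted p = 0.348 lower and 0.193 higher), nor among genes with an island (both adjusted p = 1.0). The lower ones were the homeobox genes Hoxc4 (0.746), Meis2 (0.691), Meis1 (0.812) and Barx2 (0.837) in the authors' deposited table. Of 38 H3K36 and Polycomb enzymes, 4 were lower and 6 higher (adjusted p = 1.0 and 0.154), with folds of 0.624 at the maintenance methyltransferase gene Dnmt1, 1.47 and 1.62 at the demethylase genes Kdm4b and Kdm2a, and 1.41 at Ezh2, the H3K27 methyltransferase gene, in the authors' deposited table. Squamous carcinoma genes had 4 of 37 in each direction, with 2 genes counted in both (adjusted p = 1.0 lower and 0.590 higher). Islands there included the E-cadherin gene Cdh1 at 0.663, Fat2 at 0.759, Rb1 at 1.65 and the proliferation marker Mki67 at 1.15 in the authors' deposited table. Markers of other cell types had lower islands at 2 of 7 melanocyte genes (Mitf 0.795, Dct 0.789), 1 of 14 immune genes (Itgam 0.626), 4 of 13 fibroblast and endothelial genes (Vwf 0.713, Pecam1 0.642, Tek 0.638, Fbln1 0.740) and 0 of 4 Merkel cell genes in the authors' deposited table. None of these marker lists had a higher island, and their smallest adjusted p was 0.163. Adjusted over the list alone, the number of genes with a lower island was the same in each list, and those with a higher island were 4 in place of 3 gland, 8 in place of 6 BMP and TGF-beta, and 7 in place of 6 enzyme genes, and as before in the other lists.

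Gene bodies and the space between genes differed. On the autosomes, 5904 islands outside gene bodies had a median log2 fold of -0.47 (quartiles -0.64 and -0.25), and 78.3% were lower and 7.33% higher. The 7004 islands in gene bodies had a median of -0.12 (quartiles -0.40 and 0.26), and 45.0% were lower and 25.7% higher. Of all higher islands 77.8% lay in gene bodies, against 40.5% of lower islands (odds ratio 5.15, Fisher's exact p = 7.05e-228). Among the 2631 autosomal islands of at least 7400 bp, the widest 20% with ties, these shares were 59.3% and 38.6%. The difference was smallest in the 20% of autosomal islands with the most reads per bp, where the medians were -0.01 in gene bodies and -0.10 outside them, 20.9% and 19.7% were higher, and 30.9% and 43.2% were lower. Without the V segments of the immunoglobulin heavy chain locus the values outside gene bodies there were -0.15, 14.4% and 46.2%. This densest group also holds islands outside genes with extreme read numbers, such as that on chromosome 9 from 2999801 to 3038400 (157102 mutant and 131940 WT reads). Whether blacklisted regions were removed is not given, so the smaller difference cannot be read as a property of strong H3K36me2 alone.

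**Figure D1:**
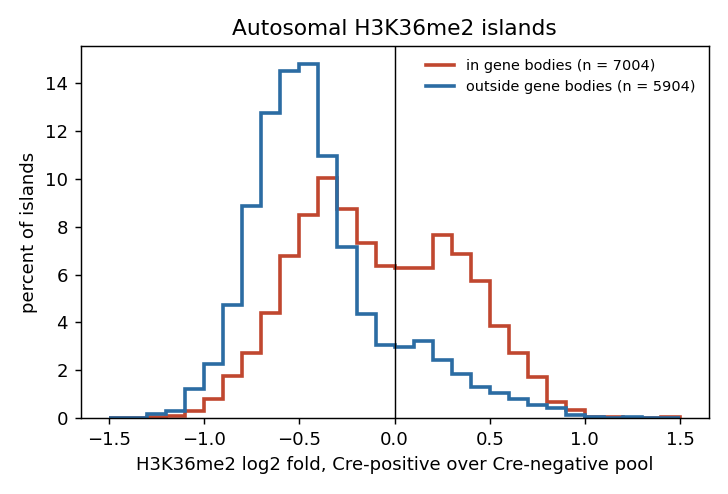
Distribution of the log2 fold of H3K36me2, mutant pool over WT pool, for autosomal islands in gene bodies (n = 7004) and outside them (n = 5904), in percent of islands per bin of 0.1, with the few values beyond the axis in the end bins. The medians are -0.12 and -0.47.

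DiffBind, which uses the spread between animals, called 0 H3K36me2 windows at FDR 0.05. The smallest FDR in the authors' deposited table was 0.139, for a window on chromosome 8 from 7493631 to 7494031. Its means were 1.22 mutant and 18.2 WT normalised reads (p = 7.71e-06 in the authors' deposited table), and the SICER2 island there had a fold of 0.431. At a nominal p under 0.05 the authors' deposited table lists 730 windows, 507 lower and 223 higher, where 903.6 of the 18072 tested are expected by chance. Lower windows had median means of 4.04 mutant and 11 WT reads, and higher windows 8.38 and 2.72. The deposited log2 folds of these windows were shrunk to a median size of 0.0029, while their genotype means differed by a median of 1.47 on the log2 scale.

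DiffBind windows and SICER2 islands, made from the same libraries, were compared next. Of the 730 nominal windows, 211 lay in an island. Of 196 lower windows in islands, 194 were in lower islands, 0 in higher ones and 2 in islands called neither way. Of 15 higher windows in islands, 11 were in higher islands, 1 in a lower one and 3 in neither. Thus 205 of 206 windows in called islands (99.5%, 95% interval 97.3 to 99.99) had the direction of the island. At Maml2, Cmss1, Ivl, Edaradd, Disp1, Gli3, Tgfbr2, Hes1, Jag1, Hoxc4, Meis2, Meis1, Dnmt1, Cdh1, Fat2, Mitf, Dct, Vwf, Pecam1, Tek and Fbln1 the island was no longer called relative to the median, and at Barx2 the log2 fold became 0.04. At Plin2, Meis1, Barx2, Mitf and Dct the binomial test at the deposited scaling made no call (adjusted p = 0.0603 to 0.175).

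The second comparison asked how H3K27me3, the Polycomb mark that H3K36 methylation limits, differed between the genotypes. H3K27me3 fell at some windows and rose at others. DiffBind called 4285 of 18072 windows (23.7%) at FDR 0.05, of which 2742 fell (64.0%, 95% interval 62.5 to 65.4) and 1543 rose. Falling windows had median means of 51.6 normalised reads in WT and 21.2 in the mutant, and rising windows 3.88 and 14.9. These levels are of windows picked by their change, and the 13787 windows not called are not among those listed, so whether strong windows in general fell is not known. The median log2 folds in the authors' deposited table were -1.10 and 1.22.

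The largest rise lay in Trp63, whose product p63 maintains stratified epithelia, on chromosome 16 from 25690029 to 25690429. Its mean went from 2.52 to 34.2 normalised reads, a log2 fold of 2.72 (FDR 2.49e-08) in the authors' deposited table. Other large rises near genes in the authors' deposited table were at Dupd1, a phosphatase gene (2.15), Togaram2 (2.10), Vav3 (2.08), Pde8a, a cAMP phosphodiesterase gene (2.07), and Zhx1, a homeobox repressor gene (2.0). Auts2, a neurodevelopmental gene (1.97), Efna5, an ephrin gene (1.94), Aff3 (1.94) and Fam114a1 (1.92) followed in the authors' deposited table. Macrod2 held 14 rising windows, Auts2 and Cep112 5 each, and Vav3 and Specc1 4 each.

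Among windows within 5 kb of a gene, the largest falls in the authors' deposited table were at Agap2, an Arf GTPase activator gene (-2.22), Nrg1, which encodes the growth factor neuregulin (-2.18), Fras1, a basement membrane gene (-2.11), and Myo5b, a recycling endosome motor gene (-2.09). Ntm (-2.04), the phosphatase gene Ptprk (-2.01), Rab3c (-1.98), the neuromedin B receptor gene Nmbr (-1.96), Adam18 (-1.96) and Fgf5, which ends hair growth (-1.95), came next in the authors' deposited table. The largest fall of all, -2.79 in the authors' deposited table, lay away from genes on chromosome 6 from 98419992 to 98420392. Rap1gap2, Prdm16, Phactr1, Dab1 and Npas3 held 6 falling windows each.

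Polycomb-bound developmental regulators had falling windows and no rising ones. Of 154, 81 had a falling window (52.6%, against 7.43% of all genes) and 0 a rising one (odds ratio 14.5, adjusted p = 1.81e-48). These genes were listed for Polycomb binding, so a fall can be seen at them more readily than at genes without the mark, and windows not called are not listed. The odds ratio is thus partly a statement of where H3K27me3 lies. Their direction differed from that of the other genes with changed windows (Fisher's exact test, adjusted p = 1.09e-09). This comparison has the same limit, as rising windows had a median WT mean of 3.88 reads and falling ones 51.6. Genes that carry the mark in WT may thus be less likely to hold a rising window. Pax2 and Pax8, kidney and thyroid regulators, had log2 folds of -1.29 and -1.27, and Emx1 and Barhl1, forebrain and sensory regulators, -1.23 and -1.22 in the authors' deposited table. The Pax2 window went from 177 to 69.2 normalised reads. Of 39 genes of the Hox family in that list, 3 had a falling window (7.69%, near the 7.43% of all genes).

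Some other lists also had more genes with falls than expected, but their direction did not differ from that of all genes with changed windows (adjusted p = 0.744 for gland and for FGF, EGF and Notch genes, 1.0 for basal and for WNT genes). The limit given for Polycomb-bound regulators holds for these lists and those below too. Their background was all protein-coding genes, whether or not these carry H3K27me3 in WT. Of 40 gland and sebaceous genes 12 had a falling window and 1 a rising one (odds ratio 5.37, adjusted p = 2.40e-04 for falls), including Nrg1 at -1.99, Msx1, a homeobox gene of appendages, at -1.58, Foxi3, of hair and tooth placodes, at -1.16 and the water channel gene Aqp5 at -1.04 in the authors' deposited table. Among the 22 genes of that list of at least 10 kb, 3 had a falling window (adjusted p = 0.784). Of 41 FGF, EGF and Notch signalling genes 13 fell and 1 rose (odds ratio 5.82, adjusted p = 9.18e-05 for falls), with Hey2 at -1.51, Dll4 at -1.54, Erbb4 at -1.30 and Fgfr1 at -1.61 in the authors' deposited table. Of 23 basal and follicle stem cell genes 8 fell and 2 rose (odds ratio 6.67, adjusted p = 0.00114 for falls, and 0.125 among the 17 of at least 10 kb). These included the follicle stem cell genes Lgr5 at -1.60 and Lhx2 at -1.5 and the integrin gene Itga3 at -1.84, besides the rise at Trp63, in the authors' deposited table. WNT genes fell at 9 of 49 and rose at 4 (adjusted p = 0.0431 for falls, 0.0891 with gene bodies only, and 0.132 for rises), with the antagonist genes Dkk1 at -1.04 and Wif1 at -1.09, the ligand gene Wnt2 at -1.23 and the effector gene Lef1 at -1.11 in the authors' deposited table.

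Merkel cell markers had a falling window at 3 of 4 genes (Fisher's exact test, adjusted p = 0.00963), but at 1 of 4 with gene bodies only (adjusted p = 0.469), with Insm1 at -1.31, Atoh1 at -0.89 and the touch channel gene Piezo2 at -0.87 in the authors' deposited table. Hedgehog genes had 4 of 16 falling and 2 rising (adjusted p = 0.1002 and 0.163), the falls being the ligand genes Ihh at -1.28, Dhh at -1.06 and Shh at -0.79 and the decoy receptor gene Hhip at -0.74 in the authors' deposited table. Squamous carcinoma genes had 7 of 37 falling and 0 rising (adjusted p = 0.0762 and 0.882), among them the mesenchymal regulators Twist2 at -1.42, Zeb1 at -1.22 and Zeb2 at -0.99 and the N-cadherin gene Cdh2 at -0.91 in the authors' deposited table. BMP and TGF-beta genes had 5 of 40 falling and 2 rising (adjusted p = 0.422 and 0.516), with the antagonist gene Grem1 at -1.32, Gdf6 at -1.0, Smad6 at -1.13 and Tgfbr3 at 1.40 in the authors' deposited table. Epidermal differentiation genes had 1 falling, Prdm1 at -1.28, and 1 rising, the loricrin gene Lor at 1.08, in the authors' deposited table (adjusted p = 0.599 and 1.0 over 38 genes). H3K36 and Polycomb enzymes had 0 of 38 falling and 1 rising, the DNA demethylation gene Tet1 at 0.87 in the authors' deposited table (adjusted p = 0.252 and 1.0).

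Markers of other cell types were also counted. Falls lay at 1 of 7 melanocyte genes (Kit, -1.82), 2 of 14 immune genes (H2-Ab1, -0.91, and Cd3g, -0.70) and 3 of 13 fibroblast and endothelial genes (Kdr, -1.30, Pdgfra, -0.86, and Dcn, -1.48) in the authors' deposited table. Rises lay at 2 of the 13 fibroblast and endothelial genes, with the endothelial adhesion gene Pecam1 at 1.90 in the authors' deposited table. The smallest adjusted p of these 3 lists was 0.140.

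**Figure D2:**
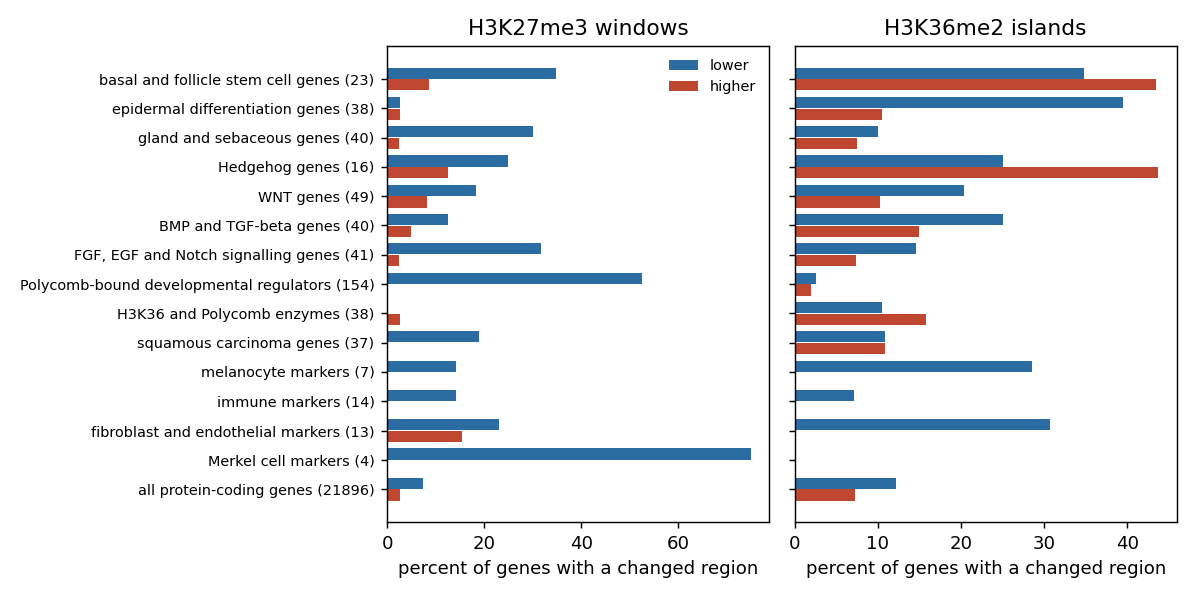
Percent of the genes of each list with a lower (blue) or higher (red) region within 5 kb, for H3K27me3 windows (left) and H3K36me2 islands (right), with list sizes in parentheses. Polycomb-bound developmental regulators had falling H3K27me3 windows at 52.6% of genes and rising ones at none.

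Falling windows lay near genes more often than rising ones. Within 1 kb of a gene end were 19.99% of falling windows (95% interval 18.5 to 21.5) and 3.18% of rising windows (2.36 to 4.18; odds ratio 7.62, Fisher's exact p = 5.10e-63). In gene bodies lay 53.5% of falling and 35.1% of rising windows (Fisher's exact p = 3.45e-31). On the X chromosome 24 windows fell and 4 rose. The WT mean was at the floor of 1 read in 105 of the listed windows and the mutant mean in 2, so the size of the rises at those 105 windows depends on the floor. At FDR 0.01, 2097 windows fell and 639 rose.

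**Figure D3:**
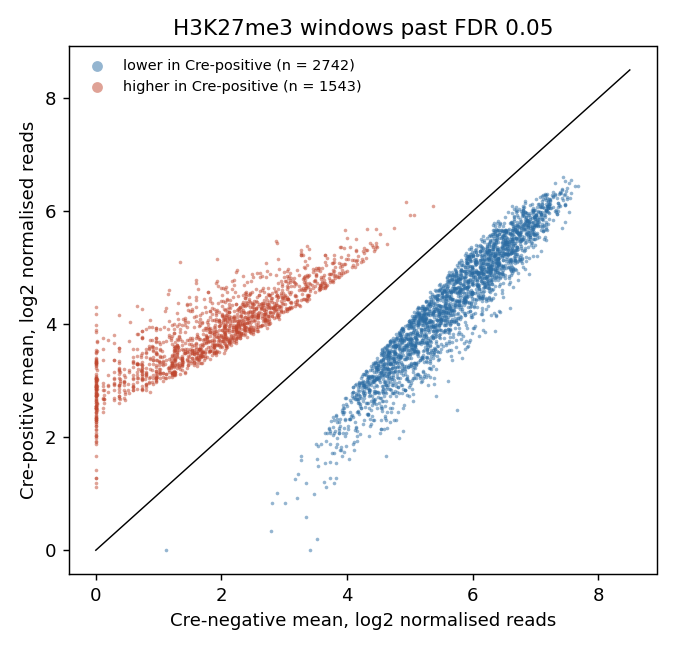
Mean H3K27me3 per 401 bp window in WT (x axis) and mutant (y axis), both in log2 normalised reads, for the 2742 falling (blue) and 1543 rising (red) windows at FDR 0.05, with the line of equal means. Medians went from 51.6 to 21.2 reads at falling windows and from 3.88 to 14.9 at rising ones.

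The third comparison set both marks side by side, to see whether places that lost H3K36me2 gained H3K27me3. Rising H3K27me3 windows lay in lower H3K36me2 islands more often than falling ones did, though 1255 of 1543 rising and 2736 of 2742 falling windows lay in no island. Of 1543 rising windows, 269 (17.4%, 95% interval 15.6 to 19.4) were in a lower island, against 1 of 2742 falling windows (0.0365%, 0.000923 to 0.203; Fisher's exact p = 7.64e-125). Higher islands held 2 rising and 1 falling window, and islands called neither way 17 and 4. With the lower islands placed at random, a mean of 33.8 rising windows lay in them (SD 5.72 over 1000 placements). That is 7.96 times fewer than observed, and no placement reached 269 (1-sided permutation p = 0.000999, the smallest they can give). The mean for falling windows was 58.8, and all 1000 placements gave at least the 1 observed. The placements are uniform, although windows of both marks lie at tested positions only: by the same placements each of the 4 combinations of nominal H3K36me2 and H3K27me3 windows was 80.5 to 381 times above its mean, windows lower in both included (38 against 0.472). The ratio to placements is therefore not a measure of how far the marks go together. The contrast of rising with falling windows rests mainly on being in an island at all, which 288 rising (18.7%) and 6 falling windows (0.219%) were. Within islands, 269 of those 288 (93.4%, 95% interval 89.9 to 96.0) and 1 of those 6 were in a lower island (Fisher's exact p = 1.36e-05), and lower islands made up 63.9% of island base pairs. Outside gene bodies the shares were 19.9% of 1001 rising and 0 of 1275 falling windows (interval up to 0.289%, Fisher's exact p = 5.09e-77), and in gene bodies 12.9% of 542 and 0.0682% of 1467 (p = 2.56e-40). With islands called relative to the median fold, 98 rising windows lay in lower islands.

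**Figure D4:**
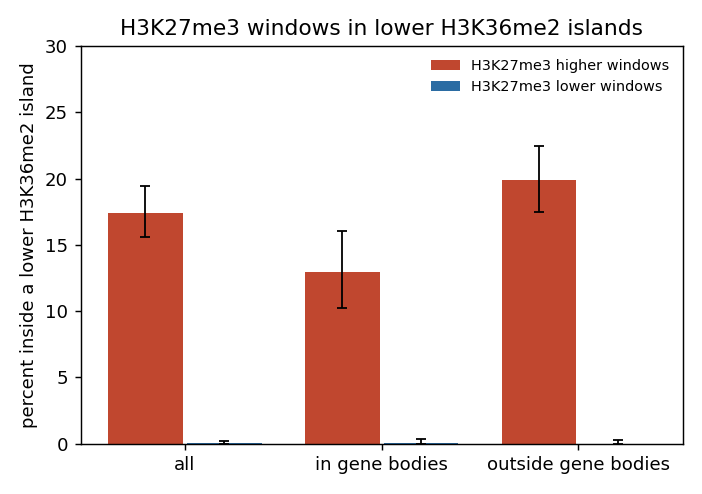
Percent of rising (red) and falling (blue) H3K27me3 windows inside a lower H3K36me2 island, for all windows and for those in and outside gene bodies, with exact 95% binomial intervals. Rising windows reach 17.4%, 12.9% and 19.9%. Only 6 of the 2742 falling windows lay in any island, so their shares under 0.1% say little about the direction of H3K36me2.

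The planned overlap of H3K27me3 windows with H3K36me2 DiffBind windows past FDR 0.05 was 0, as no H3K36me2 window passed. The nominal H3K36me2 windows shared 214 positions with the H3K27me3 windows, against 173 expected among 18072 (odds ratio 1.35, Fisher's exact p = 3.74e-04). Of these, 165 moved in opposite directions (77.1%, 95% interval 70.9 to 82.6; Fisher's exact p = 1.74e-17). Windows lower in H3K36me2 and higher in H3K27me3 numbered 88 (43.3 expected, adjusted p = 2.82e-10), and windows higher in H3K36me2 and lower in H3K27me3 numbered 77 (33.8 expected, adjusted p = 2.20e-12). Windows lower in both numbered 38 (76.9 expected, adjusted p = 2.05e-07), and windows higher in both 11 (19.0 expected, adjusted p = 0.0531). The 730 nominal H3K36me2 windows were fewer than the 903.6 expected by chance, and none passed the FDR. Both marks came from the same animals. A more even background in the mutant libraries cannot be told apart here from opposite moves of the marks.

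Counted by gene, rising H3K27me3 windows and lower H3K36me2 islands also occurred together. Long genes can hold more of both, and the expected counts below do not allow for gene length. Among genes of at least 10 kb the odds ratio was 7.49 (Fisher's exact test, adjusted p = 2.68e-100), but length was not matched further. Of 579 genes with a rising H3K27me3 window, 300 (51.8%) also had a lower H3K36me2 island, where 70.6 were expected (odds ratio 8.60, adjusted p = 1.90e-122). Among the 4512 genes with any island, 88.5% of those with a rising window had a lower island (300 genes, 201 expected, odds ratio 5.85, adjusted p = 3.43e-34). Genes with a falling H3K27me3 window had fewer lower islands (99, 198 expected, odds ratio 0.446, adjusted p = 5.88e-17) and fewer higher islands (52, 117 expected, odds ratio 0.406, adjusted p = 1.77e-12) than other genes, but among genes with any island neither differed (odds ratios 1.14 and 0.903, both adjusted p = 0.611). Genes with a rising window and a higher island numbered 80 (41.6 expected, odds ratio 2.13, adjusted p = 1.80e-08), which reversed among genes with any island (118 expected, odds ratio 0.553, adjusted p = 7.01e-06). Macrod2 had 21 lower islands and 14 rising windows, and Auts2 had 11 and 5. In the authors' deposited tables the leading genes of this kind were Phactr2, an actin regulator gene (island fold 0.569, H3K27me3 log2 fold 1.85), Fam178b (0.771 and 1.77), Prkag2, an AMPK subunit gene (0.733 and 1.76), Pecam1 (0.642 and 1.90), Aff3 (0.569 and 1.94), Auts2 (0.525 and 1.97), Vav3 (0.587 and 2.08), Togaram2 (0.602 and 2.10), Cmss1 (0.664 and 1.80) and Zhx1 (0.729 and 2.0). The islands at Fam178b, Prkag2, Pecam1, Cmss1 and Zhx1 were not called lower relative to the median fold. Each pair shares a gene but mostly not a place. Only at Zhx1 did the window lie in the island whose fold is given. At Phactr2 the island ran from 13461001 to 13465000 and the window from 13325867 to 13326267.

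Trp63 counted both among the genes with a rising window and a lower island and among those with a rising window and a higher island. Its gene body, on chromosome 16 from 25683763 to 25892088, held 12 islands, of which 5 were higher, 2 lower and 5 neither. The higher islands lay between 25768601 and 25860800, and the rising H3K27me3 window lay outside the islands, at the other end of the gene. The pooled read ratio over the 12 islands was 1.13 (exact 95% interval 1.07 to 1.19).

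**Figure D5:**
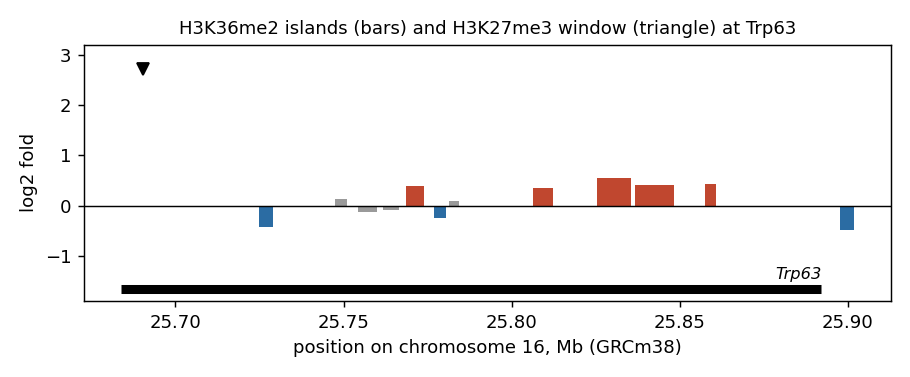
Map of Trp63 on chromosome 16 (GRCm38, in Mb) with H3K36me2 islands as bars at their log2 fold (red higher, blue lower, grey neither) and the rising H3K27me3 window as a triangle at 2.72. The black bar is the gene body.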

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

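No paired analysis was possible because the tables hold genotype means or pools and no animal is in both genotypes. Settings that need values per library (other normalisations, low-value filters, leaving out an animal, other splits of the animals, a block by animal) and those that need a transcription start site were not run, and neither was centring of the DiffBind folds, whose tables list called or nominal windows only. Tests with nominal p, gene ends, binomial tests at the deposited scaling, subsets of islands, and gene bodies, gene length, genes with any island, FDR 0.01 and other island calls for lists were chosen after the data were seen. The cause of each change below was not tested unless the alternative itself removes regions.

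With the fold divided by the median fold (0.814), the share of called islands that were lower reversed from 77.0% to 32.8% (1793 lower, 3675 higher). As this sets the median island to no change, it would also hide a general loss. All 1793 had been called lower before, and 21 lower islands became higher. Gene bodies then held 74.2% of higher and 26.2% of lower islands, 98 rising H3K27me3 windows lay in lower islands, the odds ratios for lower islands were 3.60 at epidermal differentiation genes (adjusted p = 0.172) and 0 at Polycomb regulators (0.169), that of basal genes reversed to 0 (0 of 23), and the log2 fold at Barx2 reversed to 0.039. A binomial test at the deposited scaling gave 1367 higher islands, 82.2% lower, and 79.7% of higher and 36.5% of lower islands in gene bodies.

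At FDR 0.01, 639 H3K27me3 windows rose, and the lower shares were 76.6% of H3K27me3 windows and 79.7% of islands. With an absolute log2 fold of at least 1, 1795 H3K27me3 windows fell (56.3% of those called), and 131 islands were lower and 19 higher (87.3% lower). Within 3 kb of a gene end, 1022 H3K27me3 windows fell and 145 rose (87.6% lower), and 1310 islands were lower and 442 higher (74.8% lower), as fewer regions were counted. That distance took in 37.3% of falling and 9.40% of rising windows. Counted as genes, 73.8% (H3K27me3) and 62.9% (islands) were lower, and 81.7% of island base pairs were. Without X, Y, M and the Igh V segment interval 78.5% of islands were lower. Higher islands lay in gene bodies in 80.6% of cases on autosomes, 81.5% without Igh, 59.3% in the widest 20% (38.6% of lower ones), and 50.8% in the 20% with the most reads per bp (60.05% of those without Igh).

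Nominal p gave 507 lower and 223 higher H3K36me2 windows in place of 0. With SICER2 in place of DiffBind, the planned overlap went from 0 to 269, and within 10 kb to 579 (4.47 times the placements). For the 781 rising windows near genes, placement of the 4277 lower islands near genes within gene bodies with 10 kb flanks gave 6.42 times. Neither placement keeps to tested positions. Opposite directions at shared windows made up 84.8% at H3K36me2 p under 0.01 and 83.1% at an H3K27me3 log2 fold of at least 1. With 50% of the window overlapped, 100% of windows had the island's direction.

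All 14 lists were run again in both directions and tables, adjusted over that whole family. With gene bodies only, 4 calls were lost: odds ratios of 2.77 at WNT genes (adjusted p = 0.0891) and 5.52 at Merkel cell markers (Fisher's exact, 0.469) for H3K27me3 falls, 3.76 at basal genes for lower islands (0.0700) and 5.0 at Hedgehog genes for higher islands (0.0852). Among genes of at least 10 kb the calls lost were 4.14 at basal (0.125), 1.57 at gland (0.784) and 1.65 at WNT genes (0.556) for falls, 3.64 at basal genes (0.115) and 0.383 at Polycomb regulators (0.348) for lower islands and 0.159 at Polycomb regulators for higher islands (0.193), and Merkel markers had 1 gene left and no finite odds ratio. Against genes of all biotypes, Polycomb regulators lost higher islands (0.424, adjusted p = 0.294), while calls were gained for falls at Hedgehog (6.24) and squamous carcinoma genes (4.37), lower and higher islands at BMP and TGF-beta genes (3.12 and 3.78) and higher islands at H3K36 and Polycomb enzymes (4.02). At FDR 0.01 falls at squamous carcinoma genes were called (3.56, adjusted p = 0.0329). Among genes with any island, odds ratios for lower islands were 1.10 at basal (adjusted p = 1.0), 2.60 at epidermal differentiation (0.709) and 0.459 at Polycomb genes (1.0), that for higher islands at Polycomb genes was 0.799 (1.0), and those for higher islands at basal and Hedgehog genes were called. Immune, fibroblast and endothelial, and Merkel markers gave no finite odds ratio there for lower islands. In all, 41 reruns of called lists kept their call, and 34 finite odds ratios called in neither setting crossed 1. The odds ratios of genes lower in H3K36me2 and higher in H3K27me3, and of those changed the opposite way, kept their side of 1 and a p under 0.05 with gene bodies only and among genes of at least 10 kb. Among genes with any island, that of genes higher in H3K36me2 and lower in H3K27me3 was 0.903 (Fisher's exact p = 0.611), and those of genes lower in both and higher in both reversed to 1.14 (p = 0.460) and 0.553.

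Of the 83 named islands, 58 kept their call relative to the median fold and 24 kept only their direction. Of the 76 named H3K27me3 windows, 72 passed FDR 0.01, the exceptions being Specc1, Lor, H2-Ab1 and Cd3g. The test on counts simulated with counting error only recovered 58% of islands changed 1.5-fold and 98% of those changed 2-fold. Part of the 1.5-fold changes thus went uncalled even without a spread between animals.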

Other observations

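The tests of the patterns below were chosen after the results were seen, except the spread of the fall among the strongest H3K27me3 windows. The loci of the next paragraphs were also picked after their values were seen.

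The epidermal differentiation complex, a cluster of cornified envelope genes on chromosome 3 from 90511034 to 93564645, held 38 H3K36me2 islands, of which 35 were lower, 0 higher and the median log2 fold was -0.59. The pooled read ratio was 0.687 (exact 95% interval 0.665 to 0.709), and the median lies between the quartiles of the other autosomal islands outside gene bodies (-0.64 and -0.27). H3K27me3 rose at 4 windows there and fell at 1. In Macrod2 on chromosome 2, 21 of 24 islands were lower and the pooled ratio was 0.766 (0.737 to 0.795). In Auts2 on chromosome 5, 11 of 11 islands were lower and the ratio was 0.655 (0.612 to 0.702).

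The 4 Hox clusters held 5 falling and 0 rising H3K27me3 windows, with 2 falls in Hoxd and 1 each in Hoxa, Hoxb and Hoxc. The 2 islands on the mitochondrial genome had a pooled read ratio of 1.31 (1.29 to 1.33), which is not taken as a change of H3K36me2. The median log2 fold of islands was 0.11 on the X chromosome and 0.090 on the Y chromosome, and on the autosomes it ranged from -0.42 on chromosome 13 to -0.18 on chromosome 12, which without the Igh V segment interval had -0.26, with -0.21 on chromosome 8. The Mup cluster of pheromone-binding protein genes on chromosome 4 had 13 of 17 islands higher (ratio 1.35, 1.30 to 1.41), and the Speer4 cluster on chromosome 5 had 16 of 18 higher (1.19, 1.18 to 1.21). The island over Alad and Hdhd3 on chromosome 4 was also higher (1.32, 1.23 to 1.42).

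Called H3K27me3 windows went both ways, and the levels of falling and rising ones are those of windows picked by their change. A single scaling factor as the whole of both moves is argued against, since 36.01% of the called windows rose while the rest fell, but the scaling sets where the line between rises and falls lies. For the falls alone, a smaller share of mutant reads at strong sites, with more of them elsewhere, cannot be told apart from a loss of the mark: the fifth of falling windows with the highest WT means (at least 90.9 reads) fell by a median of 1.16 on the log2 scale with an interquartile range of 0.32, but the FDR filter narrows that range and 13787 windows that were not called are not used here. For the rises, a more even background in the mutant libraries cannot be told apart from a gain either. Rises were at 17.4% of windows lower and 4.93% of windows higher in H3K36me2 (odds ratio 4.05, Fisher's exact p = 1.85e-06), which an even background alone would not give at equal WT H3K27me3, but WT means of the uncalled windows are not known. The effect of H3K36M itself stays open, as the design's biological explanation.

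The V segments of the immunoglobulin heavy chain locus (Igh), on chromosome 12 from 113572929 to 116009954, had 106 of 110 H3K36me2 islands higher (96.4%) and 0 lower, against 14 of 42 higher within 2 Mb. Their median log2 fold of 0.65 lies outside the quartiles of the other autosomal islands outside gene bodies (-0.64 and -0.27), so they did not follow the change seen there. The locus was picked after its values were seen, so this restates its rise and is no separate test. The rise was not shared by the 4 islands over V segments of the T cell receptor locus Trb (pooled ratio 0.656, 0.591 to 0.728). Tra held 0 islands and other T cell receptor loci were not examined, so T cells as a source are not decided. B cells as a source cannot be told apart either from the 3 islands of Igk (1 higher, ratio 1.13, 0.968 to 1.31). A copy number or strain difference between the animals of each genotype may explain the block (106 of 110, 96.4%), a candidate explanation found from these data. The pooled ratio of the block was 1.61 (1.58 to 1.63), and an effect of the genotype on this locus alone stays untested.

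The Krt14 island had a read ratio of 2.83 (1.60 to 5.29). The other 42 islands of the basal list had a median fold of 1.06, below the lower limit at Krt14, with 15 higher and 12 lower. These islands went both ways, and the comparison was chosen after the Krt14 value was seen. Whether a rise shared by basal keratinocyte genes is its source is therefore not decided. Extra copies of the Krt14 promoter in Cre-positive mice cannot be told apart from a rise at the gene itself. The lower limit of 1.60 is under the highest fold of the other islands, 1.83, and the labels do not give the origin or extent of the promoter. No other island lay within 5 kb of Krt14.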
